A study of Homo sapiens with 24 samples.

How the data were processed

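The series measured mRNA in RT112, an established human bladder cancer cell line, by Affymetrix 3' expression arrays. Per the labels' protocols, cells carried a doxycycline-inducible short hairpin RNA against FGFR3 or against EGFP, a jellyfish gene absent from human cells that serves as the control target. They were grown in medium with 1% serum and kept for 48 h with or without doxycycline at 1 µg/ml. Total RNA was then extracted, treated with DNase, and 3 µg of it was made into biotinylated cRNA. The labels name 4 lines, 1 with the EGFP hairpin and 3 with FGFR3 hairpins called 2-4, 4-1 and 6-16, each without and with doxycycline, giving 8 groups of 3 arrays and 24 arrays in all.

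The deposited values are log2 expression values of 54675 probe sets on each array. RMA, which corrects background, quantile-normalizes and summarises the probes of a probe set, and the affy package are named in the submitters' processing notes without versions. The probe grouping file is not given in the sources used here. The values were not centred by gene. Array medians ran from 6.98 to 7.08 on the log2 scale. No pair of arrays held identical values. An array has no read depth, so the number of arrays limits the precision. Quantile normalization gives every array nearly the same distribution, which removes any change shared by most genes.

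Probe sets were named from GEO's platform annotation. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none, and those with several or none were left out. Symbols were checked through Entrez identifiers against a RefSeq gene table of the assembly GRCh38.p14, where 41043 probe sets matched and 0 symbols changed. No coordinates are given, because the deposited values name no genome build. For a gene with several probe sets, the one with the highest mean over the 24 arrays was taken, which left 19775 genes. No filter on low values was applied.

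A single limma model (version 3.58.1 in R 4.3.3) held 1 coefficient for each of the 8 groups, so that all arrays shared 1 estimate of the spread, with 16 residual degrees of freedom and 3.13 from the empirical Bayes prior. Contrasts were the change with doxycycline in each line, the mean of the 3 FGFR3 line changes minus the EGFP line change, an F-test for differences among the 3 FGFR3 line changes, and the FGFR3 lines against the EGFP line without doxycycline. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all genes tested, and the threshold was 0.05. A gene that met the rule of the series design passed in the same direction in all 3 FGFR3 lines and did not pass in the EGFP line. Standard errors (SE) are moderated ones from this model, except those given for single probe sets, which come from the same model over all probe sets. Those of the degradation controls come from the SD pooled over the 8 groups.

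Gene lists were tested with camera, a competitive test that compares a list with all other genes, at its preset correlation of 0.01 between genes. Camera with a correlation estimated from the residuals and fry, a self-contained rotation test, were alternatives. There were 25 lists with 465 genes, of which 423 were measured. They covered lipid synthesis, MAPK output, the cell cycle, urothelial differentiation, stress and immune responses, and markers of fibroblasts and leukocytes. The lists, the contrasts, the tests and the alternatives were fixed before the data were examined, except where the closing section says otherwise.

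The genes named in the text follow a rule fixed with the design. It takes FGFR3 and TACC3, up to 12 rises and 12 falls among genes meeting the rule of the series design, and up to 4 passing members of each list or else the 1 member with the largest absolute contrast. It also takes up to 3 rises and 3 falls past the threshold in the EGFP line, 3 genes per line past the F threshold, and 4 genes at each end past the threshold between lines without doxycycline. No gene passed in any of these comparisons, so the rule gave 27 genes, FGFR3, TACC3 and 1 member of each list. Genes chosen after their values were seen are said to be so.

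The steps were tested on simulated data drawn for the 19775 genes with the residual spread found within the labelled groups. Labels were correct in these data, the changed genes were drawn at random, and the noise was independent between genes and arrays. For the change in the 2-4 line, limma recovered 39 of 50 genes changed 1.5-fold, 45 of 50 changed 2-fold and 50 of 50 changed 4-fold, with 11 false calls. For the difference between the mean FGFR3 line change and the EGFP line change it recovered 32, 42 and 49 of 50 at those fold sizes, with 7 false calls. For the rule of the series design it recovered 30, 43 and 49 of 50, with 0 false calls. In the simulated difference between lines, camera called the 1 list shifted by -0.5 on the log2 scale and 0 of the other 24. The correlation between genes estimated in the data was 0.60 for cholesterol synthesis and 0.95 for G2/M and mitosis. The simulation therefore cannot tell how often camera calls falsely where genes of a list vary together.

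Alternatives were the replicate number as a block, across all groups or within each line, and other choices of probe set per gene. Others left out probe sets that cross-hybridise or genes with a mean log2 value under 5, or applied quantile normalization or median centring. Array weights, a trended and robust prior, only the arrays of the lines compared, stricter thresholds of 0.01 or of 1.5-fold, and leaving out each array in turn were also run. Same-numbered arrays deviated together, with correlations above 0.1, in all 3 pairs of the 2-4 and 6-16 lines but not of the other lines, and the labels do not say what a number marks. The labels do not say that the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Figures were drawn with matplotlib 3.10.9.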

Results

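Expression was measured in RT112 bladder cancer cells to find the genes that depend on FGFR3, a receptor tyrosine kinase often activated in bladder cancer. Of the 4 labelled lines, 3 carried different inducible hairpins against FGFR3 and 1 carried a hairpin against EGFP. Each line had 3 arrays labelled without doxycycline and 3 labelled with 1 µg/ml doxycycline for 48 h. The 24 arrays gave values for 19775 genes. On the array's degradation controls, the 3' signal exceeded the 5' signal by 0.70 to 1.17 for ACTB and by 0.20 to 0.42 for GAPDH on the log2 scale. With doxycycline this excess differed by -0.12, -0.087, -0.037 and 0.094 for ACTB (SE 0.11) in the EGFP, 2-4, 4-1 and 6-16 lines, and by -0.058, -0.0067, 0.0020 and 0.054 for GAPDH (SE 0.053).

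The targeted gene was examined first. FGFR3 did not pass the test as lower with doxycycline in any of the 3 labelled FGFR3 hairpin lines. On the brighter of its 2 probe sets, its log2 level in the 2-4 line was 11.77 ± 0.32 (SD, n = 3) without and 11.92 ± 0.52 with doxycycline. In the 4-1 line it was 12.08 ± 0.23 without and 11.84 ± 0.49 with doxycycline. In the 6-16 line it was 11.67 ± 0.48 without and 12.09 ± 0.18 with doxycycline, and in the EGFP line 11.85 ± 0.63 and 12.01 ± 0.11. The log2 changes were 0.15, -0.24, 0.42 and 0.16 in the 2-4, 4-1, 6-16 and EGFP lines, with an SE of 0.31 each and limma adjusted p of 0.999, 1.00, 0.760 and 0.975. Averaged over the 3 FGFR3 lines the change was 0.11 with a 95% interval of -0.26 to 0.48. With 1 array left out this mean ran from 0.041 to 0.21. The change turned to -0.20 in the EGFP line without replicate 3 of the arrays without doxycycline, and to -0.061 in the 2-4 line without replicate 3 and 0.041 in the 4-1 line without replicate 1 of those with doxycycline.

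The other FGFR3 probe set gave no lower level with doxycycline in a way that passed either. On the dimmer one the log2 changes were 0.17, 0.29, -0.83 and 0.44 in the 2-4, 4-1, 6-16 and EGFP lines, with an SE of 0.62. The changes of the 4-1 and 6-16 lines on it had the opposite sign to those on the brighter one. TACC3 encodes a mitotic spindle protein and is known as the fusion partner of FGFR3 in RT112 cells. Its log2 changes were 0.28, 0.32, -0.71 and 0.19 with an SE of 0.46, and none passed limma's test. Without replicate 2 of the 2-4 arrays without doxycycline, the changes of the dimmer probe set and of TACC3 in that line were -0.51 and -0.31. Without replicate 1 of the 4-1 arrays without doxycycline they were -0.15 and 0.0073 in the 4-1 line, and without replicate 2 of the 6-16 arrays with doxycycline -0.25 and -0.24 in the 6-16 line. In the EGFP line, with 1 array left out, the dimmer probe set ran from 0.10 to 0.80 and TACC3 from 0.018 to 0.39. The hairpin's target therefore did not bear out the labels, and all groups below are named by their labels only. Every direction given below rests on those labels.

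**Figure D1:**
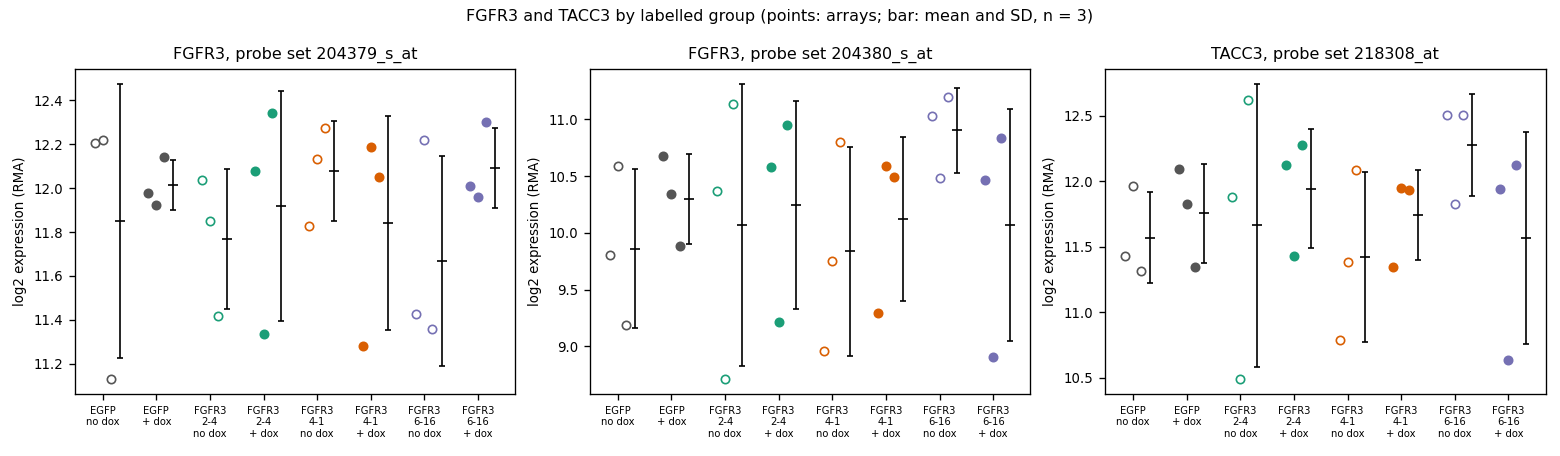
Log2 expression (RMA) on the y axis of the brighter and the dimmer FGFR3 probe set (left and middle) and of TACC3 (right) in the 8 labelled groups, with 1 point per array (filled: labelled with doxycycline) and the mean and SD of 3 arrays beside them. On the brighter one, 6 arrays lie between 11.13 and 11.43 and the other 18 between 11.83 and 12.34. Of the 6, 4 are labelled without doxycycline. On the dimmer one and on TACC3 the same 9 arrays are the lowest, at 8.71 to 9.88 and 10.49 to 11.43.

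The arrays labelled with the EGFP hairpin tested for effects of doxycycline and of hairpin induction. The lipid enzymes SQLE (squalene epoxidase) and SCD (stearoyl-CoA desaturase) had log2 changes of 0.62 ± 0.57 (SE) and 0.81 ± 0.74. ABCG1, a sterol exporter, had -1.33 ± 1.04, and IFI27, an interferon-induced gene, had 1.01 ± 0.89. With 1 array left out, SQLE ran from 0.35 to 1.13, SCD from 0.51 to 1.29, ABCG1 from -1.73 to -0.68 and IFI27 from 0.026 to 1.53. The values of -0.68 and 0.026 were those without replicate 2 of the arrays without doxycycline. None of these 4 genes passed with all arrays, and limma called 0 of 19775 genes, with 505 at an unadjusted p under 0.05 where 989 were expected by chance. Of 16 measured cholesterol synthesis enzymes, 15 had a log2 change above 0, with a median of 0.39 and a camera adjusted p of 0.00494 at the preset correlation. That p was 0.751 with an estimated correlation. The call also ended without replicate 3 of the arrays without doxycycline (median 0.26, adjusted p 0.199), or without replicate 1 (0.21, 0.184) or replicate 2 (0.31, 0.134) of those with doxycycline. The median was 0.68 without replicate 3 of the latter. Camera called 5 of 25 lists at the preset correlation, 0 with an estimated correlation, and fry called 0.

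For each FGFR3 hairpin line, arrays labelled with and without doxycycline were compared. In the 2-4 line, all 24 measured genes of G1/S and DNA replication and all 22 of G2/M and mitosis had log2 changes above 0, with medians of 0.36 and 0.32. In the 4-1 line the same held for all 24 and all 22, with medians of 0.26 and 0.26. In the 6-16 line all 24 and all 22 had changes below 0, with medians of -0.25 and -0.15. These directions rested on 1 array in each line. Each of these 3 arrays had the other 2 as its nearest arrays, so they are 1 group of like arrays under 3 labels. Without replicate 2 of the 2-4 arrays without doxycycline, the G1/S and G2/M medians were -0.053 and 0.014. Without replicate 1 of the 4-1 arrays without doxycycline they were -0.093 and -0.085, and without replicate 2 of the 6-16 arrays with doxycycline 0.12 and 0.15. None of these 6 medians was called by camera, with adjusted p of 0.350 to 0.918. The 3 arrays had an excess of 3' over 5' GAPDH signal of 0.37, 0.37 and 0.42, and of 1.17, 1.01 and 1.09 for ACTB. In the 2-4 and 6-16 lines both were the highest of the line. In the 4-1 line replicate 1 with doxycycline had the same GAPDH excess of 0.37 and a higher one for ACTB, 1.04. Without that array the G1/S and G2/M medians of the 4-1 line were 0.35 and 0.30. CDC6, which loads the replicative helicase, had changes of 0.37, 0.42 and -0.50 in the 2-4, 4-1 and 6-16 lines, with an SE of 0.50, which became -0.19, 0.015 and 0.051 without those arrays. DUSP6, a phosphatase induced by ERK signalling, had 0.07, 0.54 and -0.71 with an SE of 0.71, and -0.62, 0.10 and -0.067 without them. Camera's adjusted p for the G1/S list was 3.7e-05, 1.79e-05 and 0.000868 in the 3 lines at the preset correlation, and 0.953, 0.775 and 0.890 with an estimated correlation. Of 12 leukocyte markers, genes of another cell type, 11 were below 0 in the 2-4 line, with a median of -0.11 and a camera adjusted p of 0.0200, or adjusted p = 0.953 with an estimated correlation. That call ended without replicate 3 of the arrays without (-0.065, 0.148) or with doxycycline (-0.059, 0.141).

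Limma called 0 genes in each of the 3 FGFR3 lines. In the 6-16 line it called 1291 with array weights, 1 with the replicate block across all groups and 1 with only the arrays of that line. At an unadjusted p under 0.05 there were 487 genes in the 2-4 line, 223 in the 4-1 line and 1539 in the 6-16 line, against 989 expected by chance. In the 6-16 line 941 of these were higher and 598 lower with doxycycline, and the smallest adjusted p was 0.268. Camera called 5, 6 and 4 of 25 lists at the preset correlation, and 0 in each line with an estimated correlation or with fry. Adjusted over the list alone, 2 genes passed in the 6-16 line and 0 in the other lines. These were VIM, an intermediate filament gene, at 0.22 ± 0.07 (SE), and TYROBP, a leukocyte adaptor gene, at -0.39 ± 0.12, both named after their values were seen. Their limma adjusted p over all genes was 0.494 and 0.491.

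The series design takes as FGFR3-regulated the genes changed in all 3 FGFR3 lines and not in the EGFP line. Limma gave 0 such genes. At an unadjusted p under 0.05 in each line, 1 gene met the rule, PAMR1, named after its values were seen. Its log2 changes were -0.20, -0.23 and -0.22 in the 2-4, 4-1 and 6-16 lines with an SE of 0.09, and 0.00 in the EGFP line. The change in the 6-16 line was -0.13 without replicate 3 of the 6-16 arrays without doxycycline. Its smallest limma adjusted p was 0.604. Across genes, the changes of the lines had a Pearson correlation of -0.05 for 2-4 and 4-1, 0.23 for 2-4 and 6-16, and -0.50 for 4-1 and 6-16. The Spearman values were 0.06, 0.18 and -0.32. With 1 array left out, the Pearson values ran from -0.51 (without replicate 1 of the 4-1 arrays without doxycycline) to 0.32, from -0.13 (without replicate 3 of the 2-4 arrays without doxycycline) to 0.59, and from -0.58 to -0.26. Genes are not independent replicates, and these values describe 3 pairs of lines.

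The mean FGFR3 line change was then set against the EGFP line change directly. This contrast holds the EGFP line change with opposite sign, so it is not independent of the EGFP line values given above. Cholesterol synthesis enzymes lay lower in this contrast, with a median of -0.43 and 15 of 16 members below 0, led by SQLE at -0.78 ± 0.66 (SE). The 15 measured ribosome biogenesis genes were all below 0, with a median of -0.13, and NOP16 had -0.27 ± 0.25. Of 24 nuclear genes of oxidative phosphorylation 21 were below 0, with a median of -0.098, and the complex I gene NDUFV1 had -0.26 ± 0.18. Of 13 FOXO targets 12 were above 0, with a median of 0.17, and PDK4, which restrains pyruvate oxidation, had 0.78 ± 0.57. Camera's adjusted p for these 4 lists at the preset correlation was 0.00404, 0.0421, 0.0421 and 0.0194. Each was lost: adjusted p = 0.761 with an estimated correlation for all 4 lists.

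No member of these lists passed limma's test over all genes, and 0 passed adjusted over the list alone. Limma called 0 of 19775 genes in this contrast, with 428 at an unadjusted p under 0.05, of which 142 were above and 286 below 0. The cholesterol call also ended without replicate 3 of the EGFP arrays without doxycycline (median -0.29, adjusted p 0.155), or without replicate 1 (-0.26, 0.144) or replicate 2 (-0.33, 0.123) of those with doxycycline. Leaving out 1 of the 24 arrays ended the FOXO call in 6 cases and those of oxidative phosphorylation and ribosome biogenesis in 12 each. SQLE then ran from -1.28 to -0.51, NOP16 from -0.49 to -0.15, NDUFV1 from -0.37 to -0.12 and PDK4 from 0.52 to 1.20.

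Among the 21 lists that camera did not call in this contrast, the 24 genes of MAPK output had a median of -0.17 with 18 below 0, and DUSP6 had -0.62 ± 0.82. Fatty acid synthesis had a median of -0.26 with 15 of 19 below 0, and SCD had -0.86 ± 0.85. G1/S genes had a median of -0.12 with CDC6 at -0.28 ± 0.58, and G2/M genes a median of -0.06 with TOP2A at 0.20 ± 0.32. Luminal urothelial genes had a median of 0.20, while FABP4, the lipid chaperone among them, had -1.27 ± 1.21. Interferon-stimulated genes had a median of 0.06 with IFI27 at -0.85 ± 1.03. Of the FGF family, FGFBP1, which releases FGFs from the matrix, had -1.10 ± 0.92. Markers of other cell types were not called, with medians of -0.07 for fibroblast genes and -0.08 for leukocyte genes, whose leading members were LUM at 0.21 ± 0.21 and CD79A at -0.24 ± 0.12.

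With 1 of the 24 arrays left out, the values of this contrast kept their sign for DUSP6 (-1.12 to -0.28), SCD (-1.34 to -0.56), CDC6 (-0.57 to -0.080), TOP2A (0.067 to 0.31), FABP4 (-2.45 to -0.64), FGFBP1 (-1.71 to -0.79), LUM (0.10 to 0.31) and CD79A (-0.32 to -0.13). The median of MAPK output ran from -0.25 to -0.10, that of fatty acid synthesis from -0.36 to -0.16, that of G1/S genes from -0.24 to -0.0091 and that of luminal genes from 0.13 to 0.28. Those of fibroblast and leukocyte markers ran from -0.085 to -0.030 and from -0.14 to -0.031. The G2/M median turned to 0.055 without replicate 2 of the 6-16 arrays with doxycycline, and the interferon median to -0.085 without replicate 1 of the EGFP arrays without doxycycline. IFI27 turned to 0.14 without replicate 2 of the latter.

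**Figure D2:**
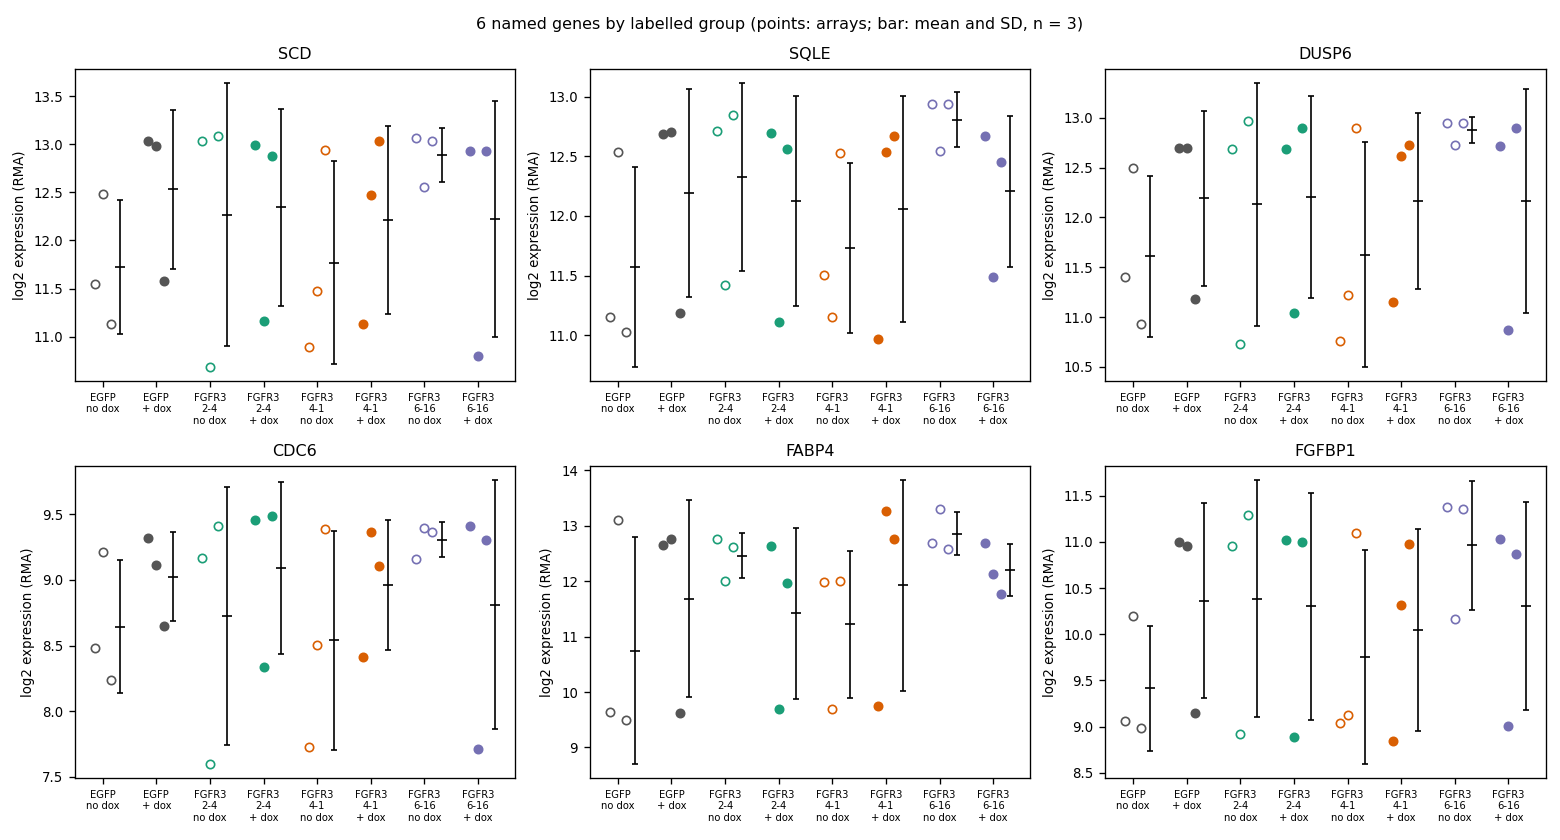
Log2 expression (RMA) on the y axis of SCD, SQLE, DUSP6, CDC6, FABP4 and FGFBP1 in the 8 labelled groups, with 1 point per array (filled: labelled with doxycycline) and the mean and SD of 3 arrays beside them. SCD runs from 10.69 to 13.09 and FABP4 from 9.50 to 13.30 over the 24 arrays. Arrays of 1 label lie far apart in some groups but not in all. The SD of DUSP6 is 1.22 in the 2-4 arrays and 0.13 in the 6-16 arrays without doxycycline.

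Differences between the 3 FGFR3 hairpins were tested with limma's F-test. Line changes of TACC3 ran from -0.71 to 0.32 and those of FABP4 from -1.03 to 0.71, and neither passed, with an adjusted p of 1.00 each. The ends of these ranges rested on single arrays. FABP4 in the 2-4 line went from -1.03 to -0.16 without replicate 2 of the arrays with doxycycline, and in the 4-1 line from 0.71 to -0.062 without replicate 2 of those without. TACC3 went from -0.71 to -0.24 in the 6-16 line and from 0.32 to 0.0073 in the 4-1 line without the arrays named above for it. The F-test called 0 of 19775 genes, with 636 at an unadjusted p under 0.05.

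The FGFR3 lines and the EGFP line were also compared without doxycycline, where the hairpins are not induced. The same arrays enter the contrast of the line changes with opposite sign, and the EGFP ones enter the EGFP line change. List shifts of opposite sign in these comparisons are therefore partly built in and are not separate evidence. All 16 cholesterol synthesis enzymes and all 24 genes of oxidative phosphorylation had higher mean levels in the FGFR3 lines, with medians of 0.41 and 0.15. Glycolysis genes were higher in 19 of 21, with a median of 0.12, and FOXO targets were lower in 12 of 13, with a median of -0.18. FABP4 had a log2 difference of 1.43 ± 0.85 (SE), SQLE 0.71 ± 0.47 and FGFR3 -0.01 ± 0.25. Without replicate 1, 2 or 3 of the EGFP arrays, FABP4 had 0.87, 2.61 and 0.81, and SQLE 0.50, 1.20 and 0.44. Limma called 0 of 19775 genes, with 576 at an unadjusted p under 0.05. Camera called 8 of 25 lists at the preset correlation, with an adjusted p of 5.81e-07 for cholesterol synthesis and 5.29e-11 for oxidative phosphorylation. Both had an adjusted p = 0.429 with an estimated correlation, under which 0 lists were called, and fry called 0. Without replicate 3 of the EGFP arrays, the medians for cholesterol synthesis and oxidative phosphorylation were 0.27 and 0.088, still called at the preset correlation (adjusted p 0.00313 and 0.000356). The FOXO call ended without replicate 1 (median -0.082, adjusted p 0.335) or replicate 3 (-0.11, 0.213) of these arrays, and its median was -0.28 without replicate 2.

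Spread within labelled groups was as wide as spread across all arrays. For cholesterol synthesis enzymes the median SD was 0.46 within labelled groups and 0.44 over all 24 arrays, and for G1/S genes 0.45 and 0.40. The labelled groups held a median of 26.4% of a gene's variance over all genes, where random groups of that size hold 30.4%. For the 1721 genes with a range over 2-fold, they held 19.2%. Over the 24 arrays, SCD ranged from 10.69 to 13.09, DUSP6 from 10.73 to 12.97 and FGFR3 from 11.13 to 12.34 on the log2 scale.

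**Figure D3:**
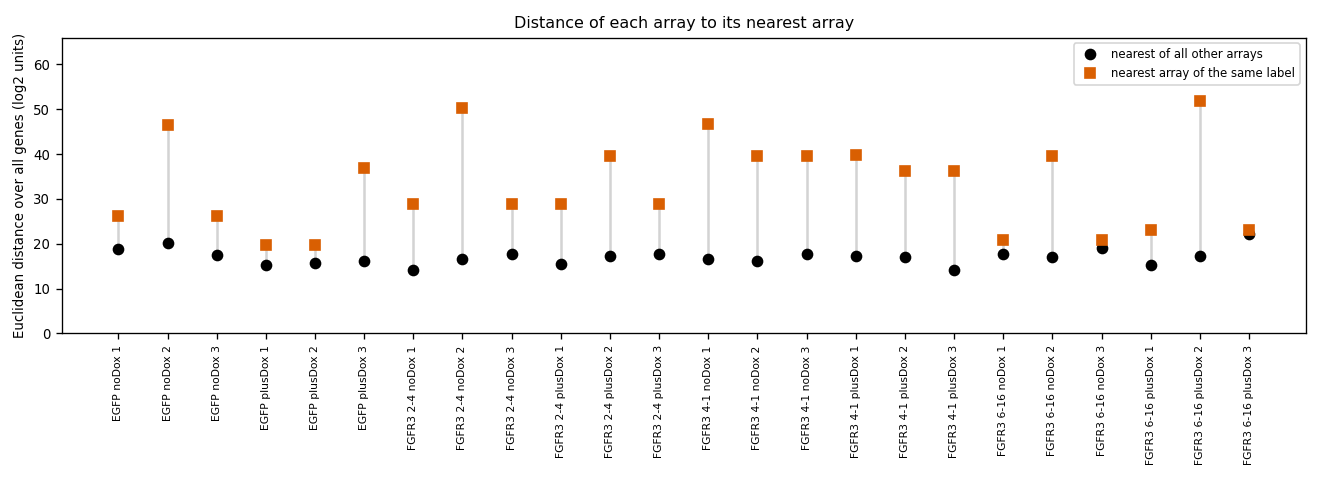
Euclidean distance over 19775 genes (log2 units) on the y axis from each of 24 arrays on the x axis to its nearest other array (circles) and to the nearest array of its own label (squares). The nearest array lies at 14.1 to 22.2 and the nearest of the same label at 19.6 to 52.0, and in 0 of 24 arrays are they the same.

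**Figure D4:**
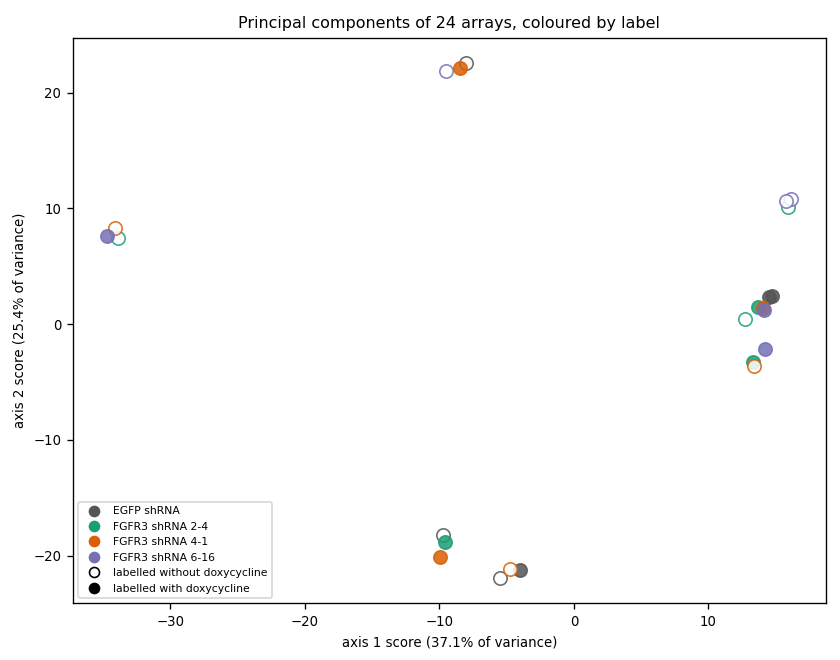
Scores of the 24 arrays on the first principal component (x axis, 37.1% of variance) and the second (y axis, 25.4%), with colour for the labelled line and filled points for arrays labelled with doxycycline. Many arrays of different labels lie together and many of the same label lie apart. Some of the same label lie close, such as replicates 1 and 2 of the EGFP arrays with doxycycline and replicates 1 and 3 of the 6-16 arrays without.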

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

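The test with an estimated correlation and the count over other splits of the arrays were read as tests of these results only after the results were seen.

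In the contrast of the mean FGFR3 line change with the EGFP line change, 4 gene lists differed between arrays labelled as FGFR3 lines and as the EGFP line by camera's test of that difference. Their median log2 shifts were -0.43 for cholesterol synthesis enzymes, -0.098 for oxidative phosphorylation, -0.13 for ribosome biogenesis and 0.17 for FOXO targets. With an estimated correlation between genes, 0 lists passed, which is consistent with members of a list varying together from array to array within a label. For the cholesterol list that estimated correlation between genes was 0.60. Of 100 splits of the arrays, 66 gave at least as many lists as the real 4. The other splits had a median of 6 lists and a highest of 14, so chance cannot be excluded. No biological explanation was tested, since FGFR3 itself did not bear out the labels.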

How the results depend on the processing

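The block made of array sets was chosen after seeing the data, and all other alternatives were planned. Counts of 0 genes held under every alternative and with each array left out (range 0 to 0), except in the 6-16 line. There, limma called 1 gene with the replicate block across all groups, 1291 with array weights and 1 with only the arrays of the lines compared, and the cause was not tested. Over all lines the replicate numbers were not taken as pairs: deviations of same-numbered arrays had correlations from -0.53 to 0.61, above 0.1 in 9 of 12 pairs, and 8 of 12 correlated best with their own number. All 3 pairs were above 0.1 in the 2-4 line (0.252 to 0.504) and in the 6-16 line (0.360 to 0.609). With the replicate block within each line, limma called 0 genes in both, and camera called 5 and 6 lists there against 5 and 4 without it, but 0 with an estimated correlation (smallest adjusted p 0.910 and 0.712) or with fry. FGFR3 changed sign with the probe set of highest variance, to 0.29 in the 4-1 line and -0.83 in the 6-16 line, and with the mean of all probe sets, to 0.0243 and -0.21. With the array sets as a block it was -0.0297 in the EGFP line and 0.0673 in the 4-1 line. Leaving out 1 array, FGFR3 ran from -0.20 to 0.35 in the EGFP line, -0.0614 to 0.44 in the 2-4 line, -0.41 to 0.0407 in the 4-1 line and 0.27 to 0.70 in the 6-16 line. None of these FGFR3 changes passed.

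The 4 called gene lists became 2 with the replicate block across all groups, 10 with the replicate block within each line, 2 with the probe set of highest variance, and 0 with an estimated correlation or fry. Oxidative phosphorylation lost its call at -0.098 with the replicate block across all groups (adjusted p 0.0549) and at -0.098 with quantile normalization (0.0618). Ribosome biogenesis lost it at -0.13 with that block (0.0549). With the probe set of highest variance they stood at -0.093 (0.444) and -0.14 (0.0871). With an estimated correlation or fry, whose medians are the same by construction, cholesterol synthesis at -0.43, oxidative phosphorylation at -0.098, ribosome biogenesis at -0.13 and FOXO targets at 0.17 were not called (0.761 and 0.826). Leaving out 1 array gave 0 to 11 called lists. Cholesterol synthesis then ran from -0.73 to -0.26 (adjusted p 1.75e-06 to 0.155) and was lost in 3 of 24 cases, all EGFP arrays. FOXO targets ran from 0.11 to 0.30 (0.000138 to 0.239) and were lost in 6, oxidative phosphorylation from -0.18 to -0.023 (1.75e-06 to 0.668) in 12, and ribosome biogenesis from -0.26 to -0.0572 (2.21e-05 to 0.626) in 12. The cause of these losses was not tested. In the contrast of the mean FGFR3 line change with the EGFP line change, the named genes other than FGFR3 kept their sign in the 260 planned values computed without leaving out arrays, with a smallest adjusted p of 0.337. With 1 array left out, IFI27 alone among them turned in that contrast (-1.37 to 0.14). Within single lines others turned too, such as CDC6 in the 2-4 line (-0.19) and in the 6-16 line (0.051), DUSP6 in the 2-4 line (-0.62) and FABP4 in the 4-1 line (-0.062).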

Other observations

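All tests in this part were chosen after the values had been seen. The arrays differed widely in gene programmes, whatever their labels. Principal components of the 24 arrays use no labels, and their sign is set so that SCD counts as positive. On the first, with 37.1% of the variance, all 24 G1/S genes, all 22 G2/M genes, 14 of 16 cholesterol synthesis enzymes and 16 of 19 fatty acid genes lay on the side of SCD. Of 24 genes of MAPK output 17 lay there too. On the opposite side lay 15 of 20 luminal urothelial genes and 10 of 13 FOXO targets. The median loadings of the cell cycle, cholesterol, fatty acid and MAPK lists exceeded those of all 10000 random lists matched on mean expression. That of the luminal list lay below all 10000. Members of the random lists were drawn separately, so these lists lack the correlation between genes of the real ones. Lists whose genes vary together reach such extremes easily, and the percentiles are descriptive only. Part of this rested on the 3 arrays at the low end, the same 3 on which the cell cycle directions of the FGFR3 lines rested. With the component recomputed without these 3 arrays, the median loading for G1/S genes went from 2.94 to 1.25, with 22 of 24 on the side of SCD. For G2/M genes the median loading went from 2.50 to 0.38, with 18 of 22. For luminal genes it went from -1.97 to -1.01, with 13 of 20 on the opposite side. Oxidative phosphorylation genes on the side of SCD went from 12 of 24 to 24 of 24, and interferon-stimulated genes on the opposite side from 12 to 23 of 27. The component's scores had a Pearson correlation of -0.83 with the excess of 3' over 5' GAPDH signal and of -0.67 with that of ACTB, and with the 3 arrays left out of the correlation -0.72 and -0.41.

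On the second component, with 25.4% of the variance, all 24 oxidative phosphorylation genes, all 15 ribosome biogenesis genes and 15 of 16 cholesterol synthesis enzymes lay on the side of SCD. On the opposite side lay 23 of 27 interferon-stimulated genes, 13 of 14 MHC class I genes and 10 of 13 FOXO targets. Arrays that resemble each other are not independent, so these percentiles describe the 24 arrays and carry no test of a condition.

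Some genes, chosen after their values were seen, were nearly on or off. ARMCX3 lay between 4.25 and 4.93 on 6 arrays and between 9.45 and 10.31 on the rest. HCLS1, an actin regulator of blood cells, lay between 6.23 and 6.75 on 6 arrays and between 9.44 and 10.48 on the rest. MMP1, a collagenase, lay between 4.35 and 6.51 on 9 arrays and between 8.68 and 9.72 on the rest. In total 13 genes had a gap of over 2 on the log2 scale between neighbouring arrays. For 12 of them, each of the 4 labelled lines held arrays on both sides of the gap.

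Arrays with the same label did not resemble each other more than arrays with different labels. The mean distance was 39.8 between arrays of the same label and 37.7 between others, and 86.6% of 100000 random labellings gave as small a mean within labels. There were 7 sets of 3 arrays, each nearest to the other 2 of its set, against at most 2 sets in 100 shuffles of each gene. Shuffling each gene on its own removes the correlation between genes. Any real structure among arrays, batches included, could therefore exceed it, and the comparison does not tell explanations apart. A candidate explanation is labels and value columns out of register, which is consistent with the 7 sets, 0 of which is a labelled group. If the hairpins lowered FGFR3 mRNA, processing batches of 3 with correct labels would leave lower FGFR3 once the sets were a block. The mean FGFR3 line change was then 0.06 with a lower 95% bound of -0.0292, and 0 genes passed. This cannot exclude such batches, because with the labels as given nothing else in the data shows that the hairpins lowered FGFR3. The sets also came from the same values. A batch marked by the replicate number would give sets of 1 number, while 5 of the 7 sets mixed numbers.

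What stays open is which array belongs to which condition, and no array was reassigned. The sets were found from overall resemblance, so they were not taken as groups of the study and were not compared. Whether they match groups of the study under other labels is not known. The genes examined differed little within a set. The SD of the brighter FGFR3 probe set was 0.063 within sets and 0.41 within labelled groups, and that of SCD 0.055 and 0.98. As the sets were found from the same values, a small spread within them is partly built in. FGFR3 on its brighter probe set lay between 11.13 and 11.43 on 6 arrays, with 1 labelled as the EGFP line and 2 labelled with doxycycline, and between 11.83 and 12.34 on the other 18. These 6 arrays are the members of 2 of the sets. On the dimmer probe set they split by set. Of them 3 lay between 9.19 and 9.29 and 3 between 11.03 and 11.20, the 3 highest values of all 24. Over all 24 arrays, the 9 lowest on the dimmer probe set lay between 8.71 and 9.88, and the next at 10.345. The same 9 arrays were the lowest on TACC3, between 10.49 and 11.43, with the next at 11.825. These 9 are the members of 3 of the sets, under labels that include the EGFP line and arrays without doxycycline. The gaps above them were 0.465 and 0.395, and gaps of 0.46 and 0.521 lay among them. No biological explanation was tested. The counts of 0 genes in the report therefore describe the labelled groups only. In simulated data of this spread, limma recovered at least 49 of 50 genes changed 4-fold. That held for the 2-4 line change, the difference between lines and the rule of the series design, and the other comparisons were not simulated. The simulation took correct labels and genes drawn at random. It says little about genes of wide spread, such as SCD and FABP4, with SEs of 0.74 and 1.04 for a line change.

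For each of the 4 line changes, the 10 splits of its 6 arrays were too few for a share under 0.05. The real count was 0 and the highest other was 0, and 10 of 10 splits gave as many genes. For the rule over 3 lines and for the F-test, the real count was 0 and the highest other was 0 in 100 splits. For the contrast of the mean FGFR3 change with the EGFP change, and for the lines without doxycycline, the real count was 0. All 100 splits gave as many in these 4 comparisons, as any split must where the real count is 0, so these shares say nothing about chance. In the last 2 the highest others were 1031 and 1035 genes, with a median of 0 over the other splits. A highest count alone does not tell what lies behind it. Dealing the arrays at random to the 8 groups gave up to 2914 calls over the 4 line changes, with calls in 11 of the 100 deals, the real one included, which had 0.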
